A study of Mus musculus with 9 samples.

How the data were processed

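RNA was measured in ears of C57BL/6 mice by 3' tag RNA-Seq, in which each transcript is read near its 3' end. The 9 libraries form 3 groups of 3 according to genotype and injected DNA. Wild-type mice received minicircle DNA coding for green fluorescent protein (GFP) or for interleukin 23 (IL-23), and Mdl-1-/- mice received the IL-23 minicircle. A minicircle is a small DNA circle without a bacterial backbone, here delivered by hydrodynamic tail vein injection at 15 µg. The mice were 10 weeks old, per the labels. The labels number the libraries of each group 1 to 3 and do not state that each came from a separate animal, so p-values measure the spread between these libraries.

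The authors' deposited count tables hold raw counts per Ensembl gene for each pair of groups. Per the submitters' processing notes, reads were handled with STAR 2.7.0a, featureCounts and edgeR, and the genome build is given as GRCh38.p6. That is a human build name, while the gene identifiers in the tables are those of mouse; the build used for alignment is therefore uncertain. The annotation release and the settings for strand and for reads that match several places are not given in the sources used here. The deposited tables of the authors' own edgeR comparisons hold log2 fold changes and mean log2 CPM (counts scaled to a library total of 1e+06) by the authors, with p-values and false discovery rates by the authors. They were used for the count of genes below a false discovery rate of 0.05 and for the overlap and direction of those genes with the calls made here.

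Each library stands in 2 of the 3 count tables with identical values (0 values differed), so the tables were joined into 1 matrix of 54838 genes and 9 libraries. Gene symbols and positions were taken by Ensembl identifier from GENCODE M21 on GRCm38, and 115 genes had no symbol; these held 0.0109% to 0.0329% of the counts of a library. No count was recorded in any library for 25446 genes. Libraries of the same group differed by more than sampling noise, with a chi-square per gene of 4.60 or more, so no pair was taken as copies of 1 library. Separate preparations of 1 animal would differ in this way too, so it does not show separate animals. Totals ran from 3776188 to 5605713 counts, which is 6.29 to 9.34 times the mean of 600000 reads per sample that the labels state. In the deepest library a count of 0 allows up to 0.535 CPM, and in the shallowest up to 0.794 CPM, taking 3 counts as the limit. Intervals and such limits cover counting error only.

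Some reads were counted at more than 1 place. The counts of 5 nuclear copies of mitochondrial genes followed mt-Co2, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l at ratios of 1.02 to 1.05 in all 9 libraries. Values of genes with near-identical copies, among them the Sprr2, Lce3 and Krt6 families, are therefore uncertain in level. As the strand setting is not given, the same holds for genes that overlap others or have an antisense partner.

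Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 13807 genes. Library sizes were scaled by trimmed mean of M-values (TMM), 1 model with 3 group means was fitted to all 9 libraries, and the quasi-likelihood F-test with robust dispersions had 6 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Standard errors of log2 fold changes were derived from the F statistic. Values given as CPM ± SD are TMM-scaled and have n = 3. Where a group had no count of a gene, the fold is a lower bound against 3 counts over the group; where it had 1 to 3 counts, the ratio of pooled CPM is given with an exact 95% interval.

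Of 29 gene lists for cell types and pathways, 27 had at least 3 tested genes (those for B and plasma cells and for eosinophils did not) and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists. With DESeq2, lists were tested by cameraPR on its Wald statistics at the same correlation. Camera with an estimated correlation and fry, a rotation test of the list itself, were alternatives. A list score is the mean over its tested genes of log2 CPM minus the mean of the wild-type GFP libraries. Counts of list genes that rose or fell are out of tested members only. These were 15 of 26 listed for T and innate lymphoid cells and 7 of 16 for type 17 cytokines and receptors. A low gene read in only 1 group could pass the filter, so shares that rose or fell may be overstated.

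Tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the procedure recovered 53% and 89% of them for wild-type IL-23 against GFP, 47% and 86% for Mdl-1-/- against wild type under IL-23, and 41% and 88% for Mdl-1-/- IL-23 against wild-type GFP. The 20 tested monocyte and macrophage genes were also raised 2-fold in the same simulated counts. False calls made up 4.43%, 3.52% and 10.0% of all calls in these 3 simulations, those of that list included. The last share lay above the 0.05 that the adjusted p aims at.

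The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Clec5a, Tyrobp and Hcst; the 8 largest rises and 8 largest falls among called genes; up to 4 members of each list with the smallest p; and Il17a, Il17f, Il22, Il23a, Il23r and Tnf. Predicted genes and pseudogenes are counted and not named, and the text gives a choice of the genes the rule names; the others are not reported here. S100a8 and Cd74 were outside the rule in the comparison of genotypes under IL-23 and were added there after their values were seen. Alternatives were other scaling, filters, dispersion settings, DESeq2 1.42.0, limma voom with sample weights, fits of only the groups compared, a replicate block and leaving out each library. A fit of protein-coding genes only and one without mitochondrial genes and their nuclear copies were added after seeing the data. No Mdl-1-/- group with GFP DNA was analysed here, so an interaction of genotype and treatment could not be fitted.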

Results

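The ear transcriptome was measured in 3 groups of 3 libraries to compare IL-23-induced skin inflammation between wild-type and Mdl-1-/- mice. MDL-1 is a myeloid surface receptor encoded by Clec5a that signals through the adaptor proteins DAP12 (Tyrobp) and DAP10 (Hcst). Wild-type mice with GFP DNA served as controls for wild-type mice with IL-23 DNA, and Mdl-1-/- mice received IL-23 DNA. Without Mdl-1-/- libraries with GFP DNA, a genotype difference present before IL-23 could not be told from a response that depends on MDL-1. Total counts averaged 5090852 ± 451975 in the wild-type GFP group, 4524552 ± 677592 in the wild-type IL-23 group and 4447153 ± 256067 in the Mdl-1-/- IL-23 group (SD, n = 3). The totals of the wild-type IL-23 group did not differ detectably from those of the GFP group (exact permutation test, two-sided, p = 0.4) or of the Mdl-1-/- group (exact p = 0.9). Between the GFP and Mdl-1-/- groups the exact p was 0.1, the smallest that 3 libraries against 3 can give. Mitochondrially encoded genes took 14.0% ± 1.31 of counts with GFP DNA, 8.85% ± 0.153 in wild type with IL-23 DNA and 12.2% ± 0.783 in Mdl-1-/- with IL-23 DNA (SD, n = 3). The exact permutation p of that percentage was 0.1 for wild-type IL-23 against GFP, 0.1 for Mdl-1-/- against wild type under IL-23 and 0.2 for Mdl-1-/- IL-23 against GFP. The first principal component held 61.0% of the variance, with the Mdl-1-/- libraries between the wild-type groups, and the second held 12.4%. On the second the Mdl-1-/- libraries lay apart from both wild-type groups, at -28.3, -30.4 and -37.3 against 4.86 to 29.4. What sets them apart there was not tested.

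Clec5a was read in every library, including those of the Mdl-1-/- group. The gene (ENSMUSG00000029915) lies on chromosome 6 at 40574894 to 40585821 on the minus strand of GRCm38. Its counts were 2, 7 and 10 in the wild-type GFP libraries, 17, 21 and 11 in the wild-type IL-23 libraries, and 10, 13 and 5 in the Mdl-1-/- libraries. Clec5a rose 3.74-fold with IL-23 DNA in wild type (log2 fold change 1.90, SE 0.49, edgeR adjusted p = 0.00554). Its log2 difference between Mdl-1-/- and wild type under IL-23 was -0.92 (SE 0.47, adjusted p = 0.185), so no difference was detectable at this depth. Hcst, too low to be tested, had 3, 6 and 6 counts in the GFP libraries, 4, 9 and 11 in the wild-type IL-23 libraries and 7, 9 and 11 in the Mdl-1-/- libraries. The deleted part of Clec5a is not named in the labels, and a 3' tag outside it does not check the genotype, so the knockout groups are named here as labelled.

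With IL-23 DNA, the lists called as higher in wild-type ear included stress keratins and the cornified envelope, the IL-17 and IL-22 response, and neutrophils, none of them called with an estimated correlation (adjusted p = 0.201 to 0.235). Those called as lower included adipocytes, cartilage, Schwann cells and skeletal muscle, likewise not called with an estimated correlation (adjusted p = 0.201 to 0.527). All 32 tested genes for stress keratins and the cornified envelope rose, with a median log2 fold change of 6.79 (6.71 with the gene that is at 0 in the GFP group set to its bound). Krt17, a keratin of wounded epidermis (chromosome 11, 100256217 to 100261029, minus strand), went from 31.5 ± 7.88 to 404 ± 73.0 CPM (12.8-fold). The envelope precursor Sprr2e rose 443-fold, and Lce3b rose from 2 counts over the GFP group to 2269, a ratio of 1276 (95% interval 353 to 10550). Of 36 genes of terminal epidermal differentiation 18 rose and 2 fell; Krt1 rose 22.8-fold and Casp14, a protease of cornification, 16.2-fold. Among 12 basal keratinocyte genes 5 fell and 1 rose. Krt15 fell 11.5-fold and Col17a1, which anchors basal cells, 4.87-fold, while Krt14 rose 2.34-fold. Adjusted over the list alone, 21 terminal differentiation genes rose and the other counts were the same. The camera adjusted p was 5.35e-46 for stress keratins (0.201 with an estimated correlation), 1.53e-08 for terminal differentiation (0.314) and 0.0311 for basal keratinocytes (0.434). The basal list also lost its call at the preset correlation without GFP library 2 (adjusted p = 0.127) or wild-type IL-23 library 2 (0.0549).

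The epidermal response to IL-17 and IL-22 rose in 16 of 19 tested genes (17 adjusted over the list alone), with a median log2 fold change of 4.36. The antimicrobial genes S100a7a and Defb4 rose 139-fold and 40.6-fold. Il22 had no count in the GFP libraries and 28, 17 and 35 counts with IL-23 DNA, at least 30-fold higher against 3 counts over the group. Il17a had 0, 0 and 0 counts in the GFP libraries and 6, 0 and 4 in the wild-type IL-23 libraries, and Il17f had 0, 0 and 0 against 1, 1 and 3. Il23a had 2, 1 and 0 against 2, 1 and 1 counts and Il23r 1, 1 and 2 against 1, 1 and 2, and these 4 genes were too low to be tested. Of 7 type 17 cytokine and receptor genes 5 rose and 1 fell, with the same counts adjusted over the list alone. They included the chemokine receptor gene Ccr6 (14.0-fold higher). Camera gave an adjusted p of 1.66e-12 for the IL-17 and IL-22 response (0.201 with an estimated correlation) and 0.0274 for the type 17 list (0.215), whose call was lost with the filter at a minimum count of 30 (adjusted p = 0.429).

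In the same comparison 12 of 15 neutrophil genes rose and 1 fell. The calprotectin gene S100a8 (chromosome 3, 90668978 to 90670035, plus strand) went from 211 ± 64.2 to 42220 ± 16260 CPM (200-fold); keratinocytes also express it. The neutrophil chemokine receptor gene Cxcr2 rose 13.2-fold. Of 14 dendritic and Langerhans cell genes 11 rose, among them H2-Aa (3.35-fold) and Cd74 (3.07-fold) of antigen presentation. In the list for MDL-1 and DAP12 signalling 11 of 16 rose, with Tyrobp 3.23-fold and the signalling adaptor Lcp2 5.96-fold higher. Of 15 T and innate lymphoid cell genes 7 rose, with the costimulatory receptor Icos 11.9-fold higher, and of 19 inflammatory cytokine and chemokine genes 11 rose and 2 fell. Tnf rose 5.95-fold, and Il1rn, which encodes the interleukin 1 receptor antagonist (chromosome 2, 24336853 to 24351494, plus strand), rose 5.49-fold. Of 31 proliferation genes 14 rose and 1 fell, with Birc5 2.75-fold higher. Adjusted over the list alone, 13 neutrophil genes rose, 1 gene of DAP12 signalling fell, and the other counts were the same. The camera adjusted p was 7.47e-06 for neutrophils (0.235 with an estimated correlation), 1.19e-06 for dendritic and Langerhans cells (0.215) and 0.000535 for DAP12 signalling (0.215). It was 0.0234 for T cells (0.314 with an estimated correlation), 0.00128 for cytokines (0.215) and 0.00104 for proliferation (0.517).

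With IL-23 DNA in wild type, 14 of 16 adipocyte genes fell and 1 rose, with Plin1, a lipid droplet coat gene, 5.24-fold lower. Of 16 cartilage genes 11 fell and 1 rose, with the collagen gene Col9a1 (chromosome 1, 24177610 to 24252684, plus strand) 7.56-fold lower. Of 8 Schwann cell genes 7 fell; S100b fell 4.69-fold, and the exception was Mbp, which rose 2.13-fold. Of 20 genes of sebaceous lipid synthesis 13 fell and 3 rose, with the fatty acid elongase gene Elovl5 3.44-fold lower. Of 21 skeletal muscle genes 9 fell, with Myh2 6.15-fold lower. There were 13 cartilage genes that fell adjusted over the list alone, and the other counts were the same. Camera gave an adjusted p of 3.51e-05 for adipocytes (0.215 with an estimated correlation), 1.21e-05 for cartilage (0.201) and 0.000975 for Schwann cells (0.215). It was 0.000535 for sebaceous synthesis (0.314 with an estimated correlation) and 0.000371 for muscle (0.527). The endothelium list was not called (adjusted p = 0.902). Of 15 mitochondrially encoded transcripts 8 fell and 2 rose, with the same counts adjusted over the list alone. That list was not called by camera (adjusted p = 0.0706; 0.577 with an estimated correlation) but was by fry (0.0467). It was called as lower by camera with upper-quartile scaling (adjusted p = 0.0331), without a count filter (0.0179), with DESeq2 (0.0389), with limma voom (0.0157), without GFP library 2 (0.0298) and without wild-type IL-23 library 3 (0.0316).

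Between wild-type IL-23 and GFP libraries edgeR called 6169 of 13807 genes, 3167 higher and 3002 lower, and 3262 of them changed at least 2-fold. Upper-quartile scaling moved the median of all genes by -0.15 (log2) and the share of calls that rose from 51.3% to 38.9%; no gene named here changed direction. The authors' deposited table lists 5315 genes at a false discovery rate under 0.05, of which 4850 were also called here, all in the same direction. Camera called 21 of 27 lists at the preset correlation and 0 with an estimated one, where 4 had an unadjusted p under 0.05, and fry called 21.

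**Figure D1:**
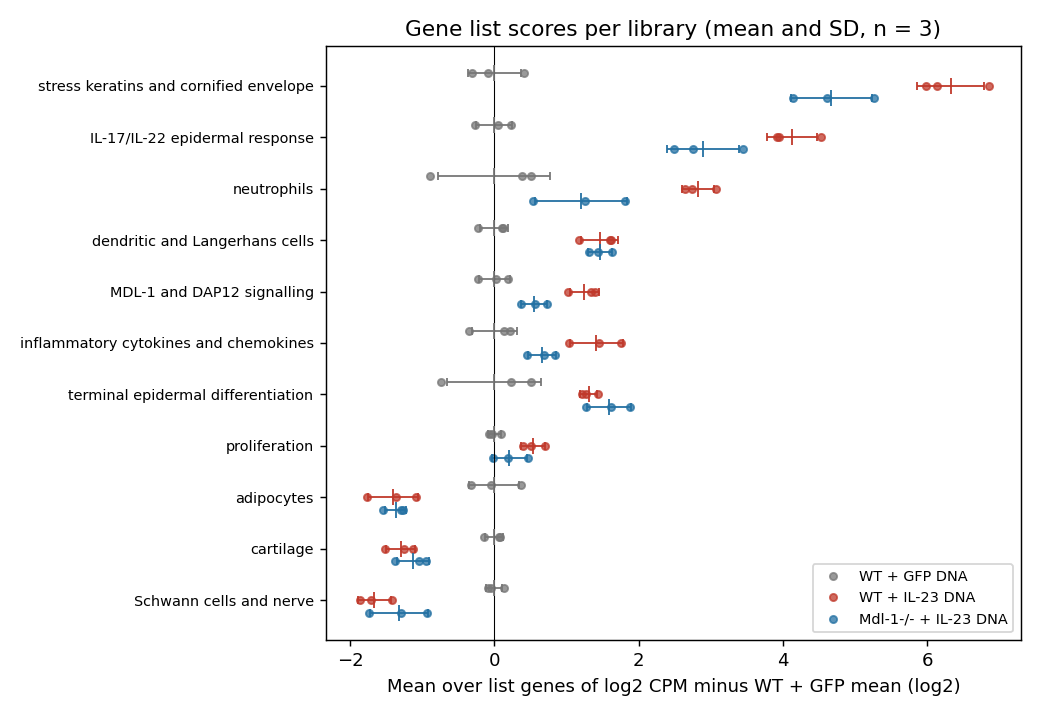
Scores of 11 gene lists in each library, as the mean over list genes of log2 CPM minus the mean of the wild-type GFP libraries (x axis, log2); points are libraries, vertical ticks are group means and horizontal bars the SD (n = 3). The stress keratin score averaged 6.32 in wild type and 4.67 in Mdl-1-/- with IL-23 DNA, while the dendritic and Langerhans cell score was 1.46 in both.

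The comparison of Mdl-1-/- with wild type, both with IL-23 DNA, asks which of these transcripts differ between the genotypes under IL-23. The lists for stress keratins, the IL-17 and IL-22 response, neutrophils, DAP12 signalling, proliferation and cytokines were called as lower in Mdl-1-/- ear; outside stress keratins a minority of the genes in each passed singly. None of these 6 lists was called with an estimated correlation (adjusted p = 0.649 to 0.869) or by fry (0.0621 to 0.168). Of 32 stress keratin and cornified envelope genes 19 fell and none rose (median log2 fold change -1.74). Krt17 went from 404 ± 73.0 to 126 ± 28.5 CPM (3.22-fold lower; log2 fold change -1.68, SE 0.20, adjusted p = 0.000671). Sprr2f and Sprr2e were 6.70-fold and 6.03-fold lower, and Gjb6, a gap junction gene, 5.32-fold lower. Of 19 genes of the IL-17 and IL-22 response 5 fell, with Defb4 4.51-fold, S100a7a 4.05-fold and Defb3 2.99-fold lower. Of 15 neutrophil genes 5 fell, with Hp, which encodes haptoglobin, 2.75-fold lower. The calls of Csf3r, Retnlg and Clec4d as lower were lost in 3, 4 and 6 of the fits that left out 1 library. Their adjusted p there reached 0.0804, 0.0884 and 0.0849. S100a8 stood at 11930 ± 7896 against 42220 ± 16260 CPM, a log2 difference of -1.82 with adjusted p = 0.0777. This gene did pass with non-robust dispersions (adjusted p = 0.009205), with DESeq2 (0.0115), with limma voom (0.00175) and without Mdl-1-/- library 2 (0.0238). Il22 had 3, 18 and 14 counts in Mdl-1-/- libraries (log2 difference -1.37, adjusted p = 0.113, or 0.0232 without a count filter), and Tnf differed by -0.75 (adjusted p = 0.202). Il17a had 0, 4 and 1 counts, Il17f 3, 0 and 0, Il23a 3, 2 and 1 and Il23r 2, 7 and 0, too low to be tested. Adjusted over the list alone, 25 stress keratin genes fell and 1 rose, 8 genes of the IL-17 and IL-22 response fell and 12 neutrophil genes fell. The camera adjusted p was 2.48e-14 for stress keratins, 0.000398 for the IL-17 and IL-22 response and 1.18e-05 for neutrophils, each with an adjusted p of 0.649 with an estimated correlation and 0.0621 with fry.

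In the MDL-1 and DAP12 signalling list 6 of 16 genes fell and none rose. Tyrobp was 2.21-fold lower (log2 fold change -1.15, SE 0.30, adjusted p = 0.0173) and Lcp2 2.82-fold lower. The Tyrobp call was lost without wild-type IL-23 library 2 (adjusted p = 0.0895) or Mdl-1-/- library 3 (0.0667), and the Lcp2 call without wild-type IL-23 library 2 (0.0553). The camera adjusted p of the list was 0.00843 (0.649 with an estimated correlation), and 0.165 with the filter at a minimum count of 30, which ended its call. Of 31 proliferation genes 8 fell and 2 rose; the mitotic genes Birc5, Plk1 and Ccna2 were 2.30-fold, 2.13-fold and 2.06-fold lower. That list had an adjusted p of 0.00258 (0.869 with an estimated correlation) and lost its call without wild-type IL-23 library 1 (0.0724). Of 19 inflammatory cytokine and chemokine genes 5 fell and 1 rose. Il1rn was 2.23-fold lower and the chemokine gene Ccl4 5.31-fold lower, and Cxcl14, a chemokine of resting epithelium, was 1.98-fold higher. The list had an adjusted p of 0.0278 (0.707 with an estimated correlation), and its call was lost without GFP library 2 (adjusted p = 0.0513), wild-type IL-23 library 3 (0.2399), Mdl-1-/- library 1 (0.0621) or Mdl-1-/- library 2 (0.0772), and with the stricter filter (0.130). Adjusted over the list alone, 8 genes of DAP12 signalling and 9 of proliferation fell, and the cytokine counts were the same. Among the largest falls were Tmprss11a, a membrane serine protease gene (14.6-fold), the ion transporter gene Slc26a4 (14.6-fold) and the phospholipase gene Pla2g4d (11.4-fold).

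Of 15 mitochondrially encoded transcripts 8 rose and 1 fell in Mdl-1-/- ear; adjusted over the list alone, 8 rose and 2 fell. mt-Co1 was 1.85-fold higher. The list had an adjusted p of 0.00843 (0.869 with an estimated correlation) and lost its call without Mdl-1-/- library 2 (0.0772). Krt10, a keratin of differentiating epidermis, rose 2.95-fold to 14870 ± 1682 CPM, while Casp14 fell 3.09-fold, and the terminal differentiation list, with 3 genes higher and 3 lower of 36, was not called (adjusted p = 0.494). Of 12 basal keratinocyte genes 2 rose and 1 fell (4 and 2 adjusted over the list alone), with Col17a1 3.24-fold higher and Krt14 1.61-fold lower. The Krt14 call was lost without wild-type IL-23 library 3 (adjusted p = 0.0752), Mdl-1-/- library 1 (0.0553) or Mdl-1-/- library 3 (0.0798). The basal list was not called (adjusted p = 0.160) but was, as higher, without wild-type IL-23 library 1 (0.00306) or Mdl-1-/- library 3 (0.0243). Of the dendritic and Langerhans cell genes 1 of 14 fell and none rose, with Cd74 at a log2 difference of 0.33 (SE 0.19, adjusted p = 0.227). That list was not called (adjusted p = 0.807), nor were those for adipocytes (0.985), cartilage (0.548) and Schwann cells (0.574). Lists for monocytes and macrophages (adjusted p = 0.954) and for T and innate lymphoid cells (0.5665) were not called either. The same held for type 17 cytokines and receptors (adjusted p = 0.481), where 2 of 7 genes fell and 1 rose.

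In this comparison edgeR called 2439 of 13807 genes, 1046 higher and 1393 lower in Mdl-1-/-, 912 of them by at least 2-fold. With upper-quartile scaling the share that rose went from 42.9% to 53.2%, with no gene named here changing direction. The count fell to 1128 without wild-type IL-23 library 2, 1300 without wild-type IL-23 library 3, 1166 without Mdl-1-/- library 1 and 1363 without Mdl-1-/- library 3. The authors' deposited table lists 1662 genes at a false discovery rate under 0.05, of which 1493 were also called here, all in the same direction. Camera called 7 lists at the preset correlation, the 6 described above as lower and mitochondrial transcripts as higher. With an estimated correlation 0 lists were called and 0 had an unadjusted p under 0.05. With fry 0 were called, 8 had an unadjusted p under 0.05, and the adjusted p of those 7 ran from 0.0621 to 0.168.

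**Figure D2:**
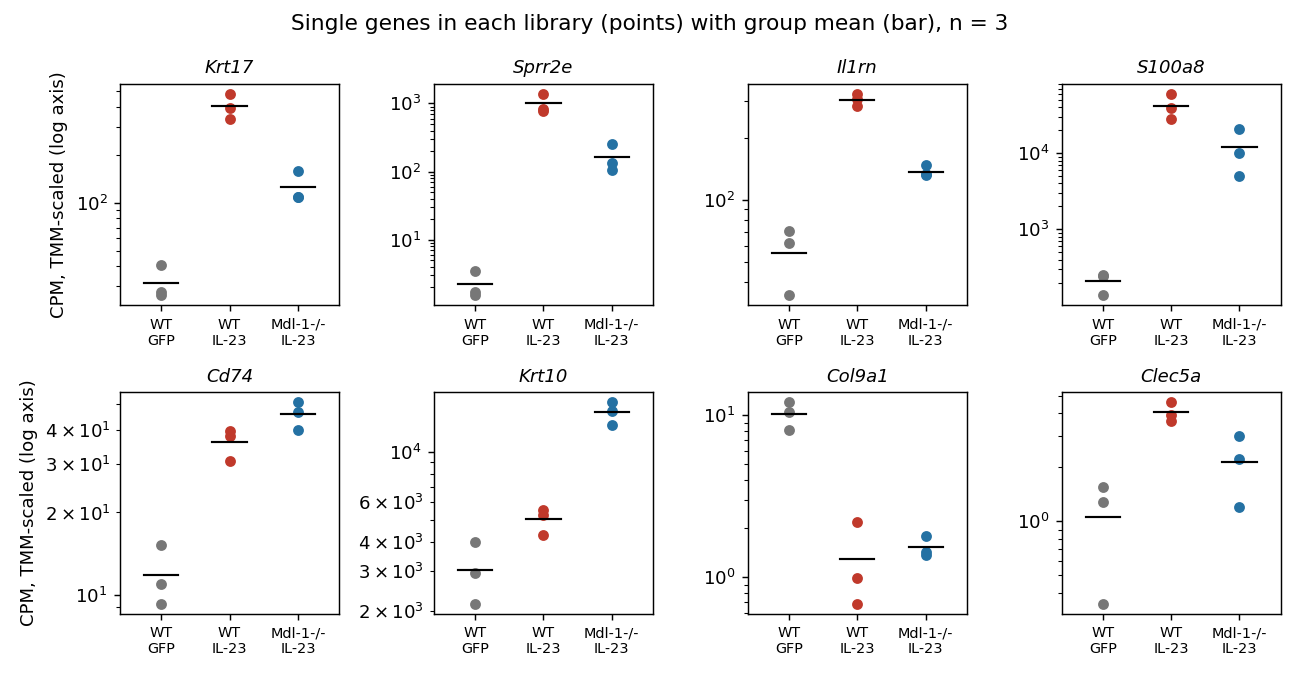
CPM after TMM scaling (y axis, logarithmic) of 8 genes in each of the 9 libraries; points are libraries and bars are group means (n = 3). Krt17 averaged 31.5, 404 and 126 CPM and Il1rn 55.6, 305 and 137 CPM in the wild-type GFP, wild-type IL-23 and Mdl-1-/- IL-23 groups, while Cd74 was at 11.8, 36.3 and 45.7 CPM.

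Set against the GFP controls, Mdl-1-/- ear with IL-23 DNA had lists called as higher for stress keratins, terminal differentiation, the IL-17 and IL-22 response, and dendritic and Langerhans cells, none of them called with an estimated correlation (adjusted p = 0.0593 to 0.0997). Genotype and treatment both differ here, so this comparison is neither effect alone. All 32 stress keratin and envelope genes were higher (median log2 fold change 5.29, or 5.25 with the gene at 0 set to its bound), with Krt17 3.99-fold higher and Lce3b at 639 against 2 counts (ratio 366, 95% interval 101 to 3027). Of 36 terminal differentiation genes 21 were higher, including Krt10 (4.92-fold) and the lipoxygenase gene Alox12b (5.25-fold), and of 14 dendritic and Langerhans cell genes 12, including Cd74 (3.87-fold), H2-Aa (3.98-fold) and Ciita, the regulator of class II genes (3.85-fold). Of 12 basal keratinocyte genes 2 were lower and none higher (2 lower and 1 higher adjusted over the list alone), and that list was not called (adjusted p = 0.117, or 0.0261 without Mdl-1-/- library 1). Of 19 genes of the IL-17 and IL-22 response 13 were higher, with S100a7a 34.4-fold higher, and Il22 was at least 13.4-fold higher against 3 counts over the GFP group. In counts adjusted over the list alone, 25 terminal differentiation genes and 17 of the IL-17 and IL-22 response were higher, and the other counts were the same. Camera gave an adjusted p of 1.82e-65 for stress keratins (0.0593 with an estimated correlation) and 5.93e-23 for terminal differentiation (0.0997). It was 1.03e-14 for dendritic and Langerhans cells (0.0593 with an estimated correlation) and 9.54e-16 for the IL-17 and IL-22 response (0.0659).

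Of 15 neutrophil genes 3 were higher and 2 lower than in the GFP controls, with S100a8 56.6-fold and Cxcr2 10.9-fold higher. The list was called (adjusted p = 0.00467; 0.396 with an estimated correlation), but not by fry (0.0826) or without GFP library 1 (0.166). Of 16 genes for MDL-1 and DAP12 signalling 1 was higher, the adaptor gene Blnk (2.55-fold), and Tyrobp had a log2 difference of 0.54 (SE 0.32, adjusted p = 0.267). The list had an adjusted p of 0.0159 (0.312 with an estimated correlation), and its call was lost with the filter at a minimum count of 30 (0.0984) and in a fit of only the 2 groups (0.0506). Clec5a differed by 0.99 (SE 0.53, adjusted p = 0.219). Tnf was 3.55-fold higher (adjusted p = 0.0142), a call lost without GFP library 1 (0.0554) or Mdl-1-/- library 2 (0.0580). Of the tissue lists, 12 of 16 adipocyte genes, 11 of 16 cartilage genes and 7 of 8 Schwann cell genes were lower, with Plin1 5.90-fold, Col9a1 6.56-fold and S100b 3.24-fold lower; 1 cartilage gene was higher. With p adjusted over the list alone, 14 adipocyte genes were lower and 1 higher and 12 cartilage genes were lower, and the counts for neutrophils, DAP12 signalling and Schwann cells were the same. The camera adjusted p was 2.54e-10 for adipocytes (0.0997 with an estimated correlation), 7.19e-09 for cartilage (0.0593) and 9.85e-06 for Schwann cells (0.0997).

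The count of called genes was 2359, 1402 higher and 957 lower, and 1126 changed at least 2-fold. It was 1340 without GFP library 3 and 1365 without Mdl-1-/- library 2. Upper-quartile scaling moved the share that was higher from 59.4% to 43.7%, with no gene named here changing direction. The authors' deposited table lists 1858 genes, of which 1689 were called here as well, all in the same direction. Camera called 19 lists at the preset correlation and 0 with an estimated one, where 9 had an unadjusted p under 0.05, and fry called 15. Any difference among the 3 groups was called for 5954 genes.

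Of the 6169 genes called with IL-23 DNA in wild type, 91.9% had a log2 difference of opposite sign between Mdl-1-/- and wild type under IL-23, called or not. As both comparisons use the wild-type IL-23 libraries, 100 simulations with the IL-23 effect and no genotype effect were run, and gave 58.1% on average (56.5% to 59.5%). These and the following simulations drew each gene independently. Their values and ranges therefore do not cover movement that genes of a library share. Among genes called in both comparisons, 1225 rose with IL-23 and were lower in Mdl-1-/-, and 808 fell with IL-23 and were higher in Mdl-1-/-; 9 were higher and 3 lower in both. Independent lists of these sizes would share 320 and 227 of the former 2 kinds, simulations with no effect in any group gave 0.030 and 0.070, and those with the IL-23 effect alone 0.28 and 0.12. The covariance of the log2 fold changes was -0.58, against -0.054 in simulations with no effect and -0.064 with the IL-23 effect alone. The correlation across genes, which are not independent replicates, was -0.74, against -0.53 and -0.15. Against the shared GFP controls, 1188 genes were higher and 790 lower in both IL-23 groups, where independent lists would share 322 and 208 and simulations without any effect 0.070 and 0.010. Simulations with the same IL-23 effect in both genotypes gave 2702 and 2554, more than were observed. The covariance was 0.76, against 0.046 with no effect and 1.39 with the same effect in both genotypes (correlation 0.82, against 0.47 and 0.96). The 3 shared libraries are too few to split, so part of each excess over independent lists may come from them.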

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

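No gene named in the text and none of the 47 list results called changed direction under the alternatives run for it. Of 34 list results not called, 14 had a median that changed sign under at least 1 alternative. With upper-quartile scaling these were endothelium with IL-23 in wild type, adipocytes between genotypes under IL-23, and matrix remodelling and mitochondrial transcripts for Mdl-1-/- IL-23 against wild-type GFP. Counts of called genes stayed within 1.5 times of their values under other scaling, filters, dispersion settings, DESeq2, limma voom and fits of only the groups compared. The same held when, as chosen after seeing the data, the fit was limited to protein-coding genes (5435, 2112 and 2112 genes for the 3 comparisons in the order reported) or left out mitochondrial genes and their copies (6144, 2424 and 2407). Leaving out each of the 9 libraries in turn gave 1128 to 2802 genes for Mdl-1-/- against wild type under IL-23, 1340 to 2580 for Mdl-1-/- IL-23 against wild-type GFP, and 88.5% to 94.71% for the share of IL-23-called genes that went the opposite way in Mdl-1-/-. With fewer libraries the power is lower by construction. Gene lists called fell from 21, 7 and 19 to 0, 0 and 0 with an estimated inter-gene correlation, which widens the null by the correlation measured within each list; fry, which asks whether a list moves and not whether it moves more than other genes, called 0 for Mdl-1-/- against wild type under IL-23, and the cause was not tested. The replicate numbers were not shown to pair the libraries. Same-numbered libraries deviated from their group means with correlations from -0.086 to 0.230, and differently numbered ones from -0.2135 to 0.1748. These overlapping ranges leave pairing undecided. A replicate block gave 6257, 2800 and 2682 genes and 6155 for any difference among the groups. The call of the melanocyte list with IL-23 in wild type was lost with it (adjusted p = 0.0715). So were those of Hdc (0.0741) and Clec4d (0.0742) between genotypes under IL-23. Where Clec5a was tested it did not pass between Mdl-1-/- and wild type under any alternative, with log2 differences from -1.21 to -0.62 when 1 library was left out; the filter at a minimum count of 30 removed it. At this depth 47% of genes changed 2-fold and 86% of those changed 4-fold in that comparison were recovered in simulated counts. Those genes were drawn from all tested genes, so these shares do not give the power at the low counts of Clec5a.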

Other observations

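The pooled mast cell value and all tests of explanations in this part, except those on other splits of the libraries, were chosen after the results were seen. Of 5 tested mast cell genes 3 fell and 1 rose with IL-23 DNA in wild type, and 3 rose and 1 fell in Mdl-1-/- against wild type under IL-23, with the same counts adjusted over the list alone. The mast cell protease genes Cpa3 and Mcpt4 were 11.3-fold and 10.1-fold lower with IL-23 DNA in wild type, and 8.26-fold and 7.56-fold higher in Mdl-1-/- than in wild type under IL-23 (edgeR adjusted p = 0.0066 and 0.0123). The Mcpt4 call was lost without Mdl-1-/- library 1 (adjusted p = 0.0709). The call of Cma1, another gene that rose in Mdl-1-/-, was lost in 6 of the fits that left out 1 library (adjusted p = 0.0541 to 0.211). Cma1 also did not pass with non-robust dispersions (0.0502), DESeq2 (0.0633) or limma voom (0.0998). Pooled over 12 mast cell genes without Hdc, the wild-type IL-23 libraries held 3.19, 6.48 and 5.56 CPM, the Mdl-1-/- libraries 26.4, 13.4 and 12.9, and the GFP libraries 37.9, 21.2 and 25.7. Hdc, the histidine decarboxylase gene that neutrophils express too, moved the other way, 9.11-fold up with IL-23 and 6.29-fold lower in Mdl-1-/-. That last call (adjusted p = 0.0256) was lost without wild-type IL-23 library 1 (0.0516), 2 (0.0697) or 3 (0.0820), without Mdl-1-/- library 1 (0.0655), without a count filter (0.0582) and with a replicate block (0.0741). The mast cell list was not called (adjusted p = 0.140 with IL-23 in wild type and 0.164 between genotypes), but was without a count filter (0.0104 and 0.0228) and, with IL-23 in wild type, by fry (0.0456). With IL-23 in wild type it was also called without GFP library 2 (0.0300), wild-type IL-23 library 3 (0.0417) or Mdl-1-/- library 1 (0.0475).

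With IL-23 DNA in wild type, camera called further gene lists at the preset correlation and did not call others. Of 22 immediate early genes 8 rose in wild type, with Btg2 4.74-fold higher and Junb, a transcription factor gene, higher by a log2 fold change of 1.58 (list adjusted p = 0.00143; 0.316 with an estimated correlation). Of 18 interferon response genes 4 rose (adjusted p = 0.0258; 0.577 with an estimated correlation; 0.0886 by fry; 0.0883 with the filter at a minimum count of 30), with Oas1a 9.74-fold higher. Adjusted over the list alone, 3 interferon genes rose. The interferon list was not called between genotypes under IL-23 (adjusted p = 0.790), but was called as higher in Mdl-1-/- without Mdl-1-/- library 1 (7.81e-05). The 3 Mdl-1-/- libraries kept -5.56%, 166% and 164% of the wild-type interferon score. Of 20 monocyte and macrophage genes 7 rose and 1 fell (adjusted p = 0.0289; 0.545 with an estimated correlation), a call lost without GFP library 3 (0.0608) or wild-type IL-23 library 3 (0.0520) and in a fit of only the 2 groups (0.0561). Of 21 fibroblast and matrix genes 9 fell and 2 rose (adjusted p = 0.0439; 0.545 with an estimated correlation; 0.0886 by fry), a call lost without GFP library 3 (0.0529), wild-type IL-23 library 2 (0.0978) or wild-type IL-23 library 3 (0.0646), with upper-quartile scaling (0.0707) and with the stricter filter (0.0571). All 3 melanocyte genes fell (adjusted p = 0.0403; 0.364 with an estimated correlation; 0.0715 with a replicate block). Lists for hair follicle (adjusted p = 0.140), red blood cells (0.337, or 0.0202 without GFP library 3) and matrix remodelling (0.596) were not called in that comparison.

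As a share of the wild-type log2 score, the effect of Mdl-1 loss appeared uneven across gene lists. The 3 Mdl-1-/- libraries kept 42.5% ± 22.6 of the neutrophil score and 44.1% ± 14.4 of the DAP12 signalling score. They kept 73.9% ± 8.96 of the stress keratin score and 100% ± 11.2 of the dendritic and Langerhans cell score (SD, n = 3). The scores take wild-type GFP libraries as the baseline for both genotypes, as no Mdl-1-/- group with GFP DNA was analysed. The mean log2 difference of the list genes, Mdl-1-/- against wild type under IL-23, was -1.54 for neutrophils and -1.61 for stress keratins. It was -0.733 for DAP12 signalling and 0.0109 for dendritic and Langerhans cells, so the order of the lists depends on the scale. The differences in the share kept between the dendritic and neutrophil lists ran from 34.4 to 92.8 percentage points over the 3 Mdl-1-/- libraries. All were above 0, so for this pair the sign did not rest on a single Mdl-1-/- library. The pair was picked after the scores were seen, and the 3 differences share the same wild-type means. A single Mdl-1-/- library carrying the pattern across lists therefore stays open. Against a response weakened by the same share in every list, 18 of 91 pairs of the 14 lists with a score of at least 1 in size differed by over 2 SD, or 14 with the error of the wild-type means added; adipocytes exceeded DAP12 signalling by 53.5 points (7.91 SD, or 3.33 with that error), cytokines by 51.0 (7.06, or 3.27) and neutrophils by 55.0 (3.85, or 2.61). The dendritic list exceeded DAP12 signalling by 55.9 points (2.43 SD, or 2.29), but stress keratins by 26.1 (2.19, or 1.78) and neutrophils by 57.5 with an SD of 31.1 (1.85, or 1.71). A common share may still account for the pattern, as pairs share lists, were looked through after the scores were seen and were not set against chance, and fry over all 14 lists left a share of 75% open (lowest adjusted p = 0.284; unadjusted 0.0253); an effect of genotype that differs between cell types stays open too.

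Lower transcripts of fat, cartilage and nerve sheath with IL-23 could come from dilution by RNA of added keratinocytes and leukocytes, which as the whole cause would lower all resident lists by like amounts. Of 21 differences between the 7 resident lists called as lower, 6 exceeded 2 times their spread (the SD over wild-type IL-23 libraries with the error of the GFP mean). Lists not called as lower were left out by this choice, among them endothelium, whose score was -0.0444 ± 0.569 in wild type with IL-23 DNA (SD, n = 3). In the largest of the 21, fibroblasts and matrix lay above Schwann cells by 1.11 with a spread of 0.366 (log2). Sebaceous synthesis lay above Schwann cells by 0.949 with a spread of 0.153. Among fat, cartilage and nerve sheath, cartilage lay above the Schwann cell list by 0.366 with a spread of 0.110. Adipocytes lay above Schwann cells by 0.261 with a spread of 0.208 and below cartilage by 0.105 with a spread of 0.256. As the pairs share lists and were not set against chance, and unequal growth of the tissues under dilution would also set lists apart, dilution as a part or the whole of the cause stays open. A different make-up of the collected pieces was not tested; the muscle score varied by an SD of 0.942 among Mdl-1-/- libraries.

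Clec5a reads in the libraries labelled Mdl-1-/- reached 58.1% of the wild-type IL-23 level. Reads assigned from wild-type libraries, if these shared a sequencing lane, would give every gene at least that share, but of 5237 genes with at least 300 counts in the wild-type IL-23 libraries 262 lay below it, down to 7.07% for Chil4. A knockout allele still read at its 3' end may give these reads: the Mdl-1-/- libraries held 28 counts, each library more than the 3 that a count of 0 allows. Relative to Tyrobp, Clec5a was at 32.1% ± 11.3 in Mdl-1-/- and 28.4% ± 4.54 in wild type under IL-23 (SD, n = 3), a difference that 3 libraries against 3 cannot settle (exact permutation test, two-sided, p = 0.7; smallest possible 0.1). Libraries without the deletion would give the same values, so the reads do not settle the genotype, and no biological explanation was tested.

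Of 154 genes called in the same direction in Mdl-1-/- against both wild-type groups, 0 lay within 20 Mb of Clec5a on chromosome 6, where 2.12 would be expected from the 190 tested genes there (Fisher's exact test, p = 0.28), too few to tell a shortage or an excess.

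The count of genes differing among the 3 groups was set beside other splits of the 9 libraries. The real split gave 5954 genes and was the only 1 of 100 splits, drawn from 280, to give as many. The highest other gave 2609. That argues against chance if the 9 libraries are independent, which the labels do not state. The count does not tell which of the groups differ. Each pair of groups has only 10 splits, too few for a share under 0.05. The real splits, in each case 1 of the 10, gave 6169, 2439 and 2359 genes for wild-type IL-23 against GFP, Mdl-1-/- against wild type under IL-23 and Mdl-1-/- IL-23 against GFP, and the highest other gave 0 in each.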
